A study of Homo sapiens with 8 samples.

How the data were processed

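Total RNA from 8 samples of the induced pluripotent stem cell line 585A1 was hybridised by the authors to Agilent one-colour arrays with Cy3, 1 sample per array, per the labels. The labels name the RNA kit and the quality instrument. The scanner, the feature extraction software and the normalization are not given in the sources used here. The deposited table holds 42545 rows and 8 columns of values on a log2 scale, with no missing values. The base of the logarithm was inferred from the range of each array (17.3 to 17.9 units). On each array the 75th percentile over all rows is about 0, and the values are not centred per probe, both as checked on the table.

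Of the rows, 140 are control spots. The other 42405 are probes, of which 27575 have 1 gene symbol, 0 have several and 14830 have none here. Symbols came from the probes' accessions (24828 probes), a current symbol (2201), a unique synonym (519) or the array's own symbol (27), matched to the RefSeq gene table of the GRCh38.p14 assembly, which was used for names alone. A gene was represented by its probe with the highest mean over the 8 arrays, which gave 19520 genes. A gene was tested if at least 2 arrays lay at or above the median of all values (−3.14 log2). This kept 13455 genes and left out 6065 as dim. XIST and Y-linked genes are in no table. Probes without a symbol were tested apart from the genes.

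Samples were grouped by the 2 dose series and the dose in the labels, giving 7 conditions, and only the shared condition (4 ng/ml bFGF, no Activin A) has 2 arrays. In R 4.3.3 with limma 3.58.1, lmFit and eBayes fitted each gene on all 8 arrays with an intercept, a term for the series, the bFGF dose and the Activin A dose. Doses were coded as the log2 of the dose plus 1 ng/ml, divided by that of 100 ng/ml, so that a coefficient is the fitted log2 change from 0 to 100 ng/ml. The fit has 4 residual degrees of freedom and the prior had 4.41. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The difference of the coefficients was tested as a contrast in the same fit.

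The 23 gene lists, the model and the rule for naming genes were set before the data were examined. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a trend. The same test with an estimated correlation called no list in either trend (smallest adjusted p = 0.149 for bFGF and 0.0568 for Activin A), with 4 and 5 lists at an unadjusted p under 0.05. The test named fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, gave 4 and 6 lists. Genes were named as up to 12 with the largest change in each direction among those past the threshold. Where fewer passed, the rule added genes with an unadjusted p under 0.05, values in the order of the doses and a difference beyond the 99th percentile between the arrays of the shared condition (0.461 log2), given as values. Members of the fixed lists could also be named.

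A fold between 100 and 0 ng/ml compares 2 single arrays. Background on each array was the 95th percentile of 109 control probes (−5.56 to −4.91 log2). A level under it was set to it, and the fold is then written as "at least". Between-array precision is known from the shared condition alone, where the median absolute difference of a gene was 0.066 and the 95th percentile 0.267. On each array 77.1% to 80.7% of genes lay above background.

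The scripts were tested on simulated data with 13455 genes and known answers. For the bFGF trend, a simulated log2 change of 1 was found in 3.2% of 125 changed genes, 2 in 66.4%, 4 in 98.4% and 8 in 100%. For Activin A the shares were 0%, 74.4%, 99.2% and 100%. Of the genes called, 3.74% were false for bFGF and 6.56% for Activin A. For the difference, 38 unchanged genes were called over 5 rounds. The simulated genes had independent noise, changes linear in the coded dose and no outlying array, so these are not error rates of the real calls.

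Alternatives set in advance were the dose as a rank, as a step from 0 and as linear, no term for the series, each series alone, quantile normalization, centring on the median, no filter and a stricter filter at the 75th percentile, the mean of the probes, eBayes with trend or robust, a threshold of 0.1, an estimated correlation, and each array left out in turn. Quantile normalization without the 20 ng/ml bFGF array, levels under background set to it before the fit, and the background bound on folds were chosen after seeing the data. No raw image or extraction files were analysed here.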

Results

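RNA from the human induced pluripotent stem cell line 585A1 was measured on 8 one-colour arrays after 7 days of culture on SNL feeder cells, a mouse fibroblast line. In the bFGF series the medium held 0, 4, 20 or 100 ng/ml basic FGF and no Activin A. In the Activin A series it held 4 ng/ml basic FGF with 0, 4, 20 or 100 ng/ml Activin A, a ligand that signals through the Nodal receptors. Each dose had 1 array, and the condition with 4 ng/ml bFGF and no Activin A occurs in both series, so it has 2 arrays and is called the shared condition here. The series as a whole concerns DNA methylation left by reprogramming and the ability of such lines to form blood cells, and these arrays ask how the culture factors alter expression. Levels are log2 values, with the 75th percentile of each array at about 0. A change is the fitted log2 change from 0 to 100 ng/ml with its standard error, from 4 doses with 1 array each.

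The 2 arrays of the shared condition differed by an SD of 0.146 log2 over 13455 genes, and their correlation across genes was 0.998, where genes are not independent replicates. POU5F1, the pluripotency factor OCT4, read 7.50 and 7.37 on them. The labels do not say whether these arrays came from separate cultures. The limma p-values of single genes measure how far these 8 arrays lie from the fitted dose lines, part of which may be purely technical. Around those lines the median over genes of the residual SD was 0.268. In the shared condition the SD per array was 0.103, but that is 1 SD taken across all genes. These measures are unlike, so the size of the gap cannot be read from them. The p-values of camera, of Fisher's exact test and of random draws of genes compare genes with each other. The array at 20 ng/ml bFGF stood apart from the doses on both sides, with a correlation across genes of 0.974 with the 4 ng/ml array and 0.972 with the 100 ng/ml array of its own series, while the latter 2 correlated at 0.989. Arrays at the ends of a series were about as far from their neighbour. The correlation was 0.973 between 0 and 4 ng/ml bFGF and 0.972 between 20 and 100 ng/ml Activin A. The number of arrays limits the precision of every value.

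The bFGF series asks which genes follow the dose of bFGF when no Activin A is added. Of 15 tested trophoblast and amnion genes in a list fixed in advance, 9 fell as the dose rose. CGA, the shared alpha subunit of the glycoprotein hormones, fell from a level of 7.46 without bFGF through 3.96 and 2.24 to 0.39 at 100 ng/ml (change −6.94 ± 0.65, adjusted p = 0.00308 by limma with Benjamini-Hochberg adjustment). CYP19A1, the aromatase that makes oestrogens, fell by 8.64 ± 0.55 (adjusted p = 0.000526) and was at least 113-fold lower at 100 than at 0 ng/ml, where its signal lay below background. HSD3B1, an enzyme of steroid hormone synthesis, fell by 7.18 ± 0.49 (adjusted p = 0.000595), at least 128-fold. The imprinted neighbours IGF2, a growth factor, and H19, a noncoding RNA, fell, with changes of −4.99 ± 0.62 (adjusted p = 0.0115) and −5.86 ± 0.39 (adjusted p = 0.000595). Of 13455 genes tested, 8 rose and 76 fell with the bFGF dose, and 1408 had an unadjusted p under 0.05, against 673 expected by chance.

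LGALS16, a placental galectin, fell with a fitted change of −9.76 ± 0.83 and was at least 191-fold lower at 100 than at 0 ng/ml. The keratin gene KRT23 fell with −8.04, the chemokine receptor gene CCR7 with −7.94 and S100P with −7.00. Several others fell to below background, so that their folds are lower limits. These are SLN (at least 291-fold), CD274, which encodes the immune checkpoint ligand PD-L1 (at least 116-fold), BCAR4 (at least 103-fold), MUC15 (at least 70.8-fold) and the placental insulin-like peptide gene INSL4 (at least 65.3-fold). With levels under background set to it, a setting chosen after seeing the data, the fitted change of LGALS16 was −7.69 and that of KRT23 −8.04, so the order of sizes is not settled. HOPX fell by 7.66 on its brightest probe, but its other probe above the filter gave −0.26, so the probes of this gene disagree in size. The adjusted p of these genes (limma) ran from 0.000176 for INSL4 to 0.0246 for MUC15. KRT23 was 267-fold and CCR7 289-fold lower at 100 than at 0 ng/ml.

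Few genes rose with bFGF. CLC, the gene of the Charcot-Leyden crystal protein, rose by 6.12 ± 0.56 (adjusted p = 0.00286, limma) and was at least 12.6-fold higher at 100 than at 0 ng/ml, with a change of 4.12 ± 0.59 when levels under background were set to it. SFRP2, a secreted modulator of WNT signalling, rose by 2.24 ± 0.29 (adjusted p = 0.0126), with levels of 0.45, 1.10, 1.87 and 2.66 over the doses. CTCFL, the germline relative of CTCF, rose by 3.53, SEMG1 by 2.93, PLA2G4C by 2.73, NLGN1 by 2.08, TSHZ3 by 1.78 and GNA14 by 1.63. Their adjusted p (limma) ran from 0.0115 for SEMG1 and PLA2G4C to 0.0425 for TSHZ3. CTCFL and SEMG1 lay below background at 0 ng/ml. After quantile normalization CTCFL, NLGN1 and TSHZ3 were no longer past the threshold. Without the 0 ng/ml array 0 genes rose past it. Not past the threshold, with readings in the order of the doses, were NPTX1 with a change of 5.32 ± 1.25 and ONECUT1 with 4.21 ± 0.78. CCDC110 (2.45 ± 0.60) was below background at 0 ng/ml, and SKINT1L (5.47 ± 1.74) at every dose but 100 ng/ml, so its order of doses is not measured.

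**Figure D1:**
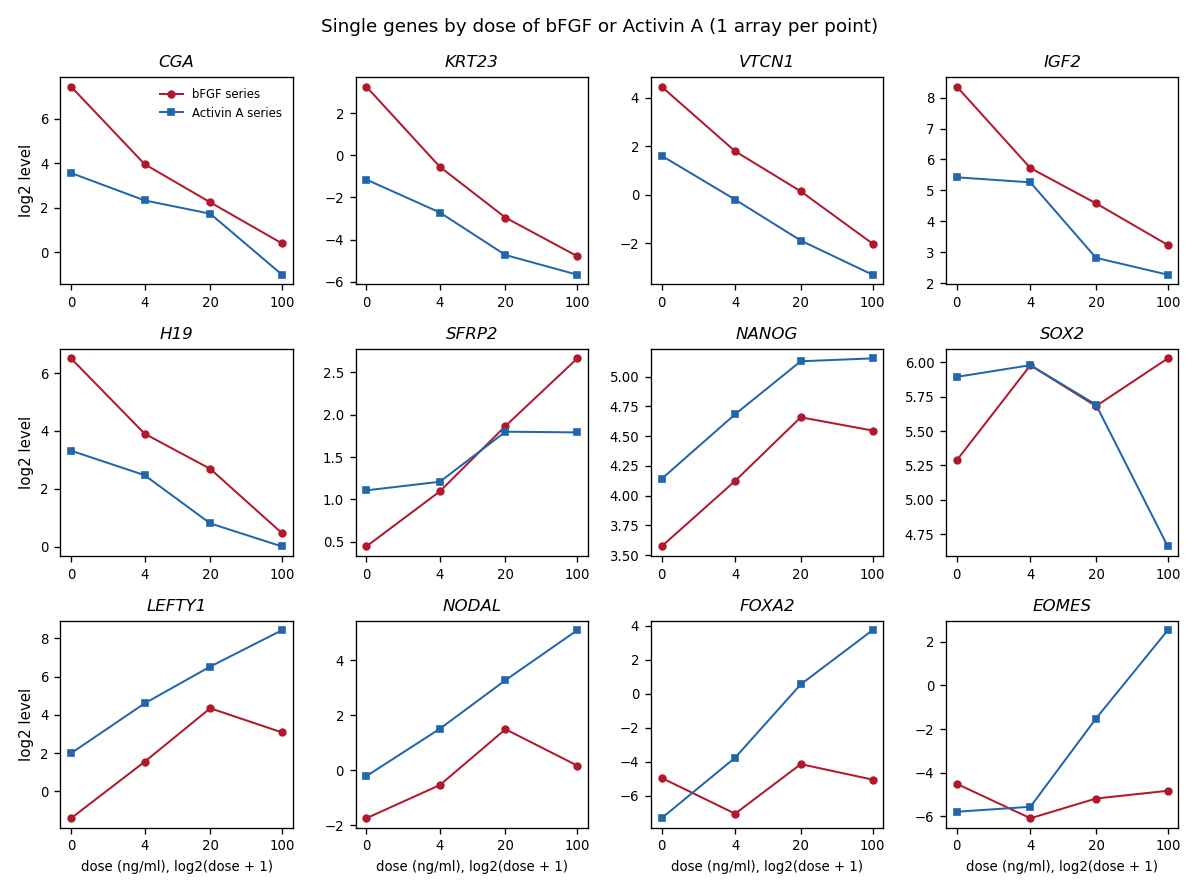
Levels of 12 genes (y axes, log2) against the dose of bFGF (circles) or Activin A (squares, with 4 ng/ml bFGF) on x axes in ng/ml spaced as log2 of the dose plus 1, with 1 array per point. CGA ran from 7.46 without bFGF to 0.39 at 100 ng/ml, and LEFTY1 from 1.99 without Activin A to 8.42 at 100 ng/ml.

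Of the 23 gene lists fixed in advance, 6 passed the list test in the bFGF series, named camera, with its preset correlation of 0.01. The trophoblast and amnion list held 15 tested genes, all with a negative change and a median of −4.45 (adjusted p = 3.02e-27, limma camera, and adjusted p = 0.149 with an estimated correlation). Its members that fell were CGA, HSD3B1, VGLL1, GABRP, GATA2, PGF, GCM1, DLX5 and HAND1, 9 in all, and all 15 passed when adjusted over the list alone. GCM1, a regulator of syncytiotrophoblast formation, fell by 4.46 ± 0.73, and PGF, placental growth factor, fell by 4.47 ± 0.75. Values for members not past the threshold were −4.45 for ISL1, −4.05 for GATA3 and −0.95 for KRT7. On the array without bFGF the definitive endoderm list's median was 0.73 (0.48 with levels under background set to it) and the fibroblast list's 0.58 relative to the shared condition, with the endoderm factor GATA6 at 2.38. At 20 and 100 ng/ml bFGF the endoderm median was 0.89 and 0.49, and the fibroblast median 0.42 and −0.02. The feeder cells are fibroblasts as well, and a part of their RNA in the fibroblast values was not tested.

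The naive pluripotency list had a median of −1.47 over 11 genes (adjusted p = 5.16e-05, limma camera, and adjusted p = 0.149 with an estimated correlation). None of its genes passed over all genes tested, while 1 rose and 6 fell when adjusted over the list alone. TBX3 had a change of −5.62 ± 1.02, SUSD2 −1.79 ± 0.47, TFCP2L1 −1.62 ± 0.36 and KLF4 −1.56 ± 0.31, against 1.77 ± 0.49 for NR5A2. The core pluripotency list moved the other way, with a median of 0.58, 16 of 18 genes positive and none past the threshold alone (adjusted p = 0.00243, limma camera, and adjusted p = 0.667 with an estimated correlation). In that list NANOG had a change of 1.04 ± 0.33, SOX2 0.59 ± 0.41 and POU5F1 0.25 ± 0.40. Relative to the shared condition, the median core gene was −0.43 without bFGF, and the trophoblast list stood at 2.34 on the same array.

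Feedback genes of the FGF/ERK pathway were shifted up, with a median of 0.68 over 21 genes (adjusted p = 0.00243, limma camera, and adjusted p = 0.149 with an estimated correlation). No member passed over all genes, and 1 rose when adjusted over the list alone. SPRY4, a feedback inhibitor of receptor signalling, had a change of 1.55 ± 0.28. DUSP6, an ERK phosphatase, had 1.99 ± 0.75 but was not in the order of the doses. It read 0.88, 0.82 and 2.81 above the shared condition at 0, 20 and 100 ng/ml. Without bFGF the list's median was −0.12 on that scale, with 2 genes at least 1 higher and 1 at least 1 lower. The list was not past the threshold without the 100 ng/ml array or with a step from 0 to any dose. BMP targets were shifted down with a median of −0.98 over 11 genes and none past the threshold (adjusted p = 0.0183, limma camera, and adjusted p = 0.536 with an estimated correlation). Of the 11 changes 9 were negative, such as those of the BMP ligand gene BMP4 at −1.27 ± 0.39 and of BAMBI at −1.06 ± 0.39. Not all ID genes fell steadily. Relative to the shared condition, at 0, 20 and 100 ng/ml, ID2 read 0.76, −0.49 and −0.24 and ID1 0.11, 0.69 and −0.28. On the same scale ID3 read 0.02, 0.47 and 0.11 and ID4 −0.13, −0.56 and −0.17. In the IGF axis and imprinted list 2 of 18 genes fell, IGF2 and H19, and 4 fell when adjusted over the list alone. Its median was only −0.14 but its mean −0.82 (adjusted p = 0.0305, limma camera, and adjusted p = 0.261 with an estimated correlation), and CDKN1C stood at −3.17 ± 0.57 (adjusted p = 0.0596).

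The count of 84 genes rests on single arrays. It was 6 without the 0 ng/ml array (199 at an unadjusted p under 0.05), 13 without 20 ng/ml (2872 unadjusted), 416 without 100 ng/ml, and 180 and 138 without the shared-condition array of the bFGF and of the Activin A series. Taking the dose linearly left 2 genes, none of them among the 84, and the core pluripotency, BMP and IGF axis lists were not past the threshold under that coding.

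The Activin A series asks which genes follow Activin A at a constant low dose of bFGF. Several genes of the primitive streak and definitive endoderm rose. FOXA2, an endoderm transcription factor, rose by 11.33 ± 1.04 (adjusted p = 0.00681, limma) and was at least 587-fold higher at 100 than at 0 ng/ml. CER1, a secreted antagonist of Nodal and BMP, rose by 11.24 ± 0.99 (adjusted p = 0.00565, at least 428-fold), GSC, a homeobox gene of the organizer, by 9.17 ± 1.06 (adjusted p = 0.0116, 750-fold) and EOMES, a T-box factor, by 8.74 ± 1.18 (adjusted p = 0.0166, at least 253-fold). NODAL and its feedback inhibitor genes LEFTY1 and LEFTY2 rose by 5.33 ± 0.78 (39.3-fold), 6.41 ± 1.11 (85.9-fold) and 7.47 ± 1.10 (179-fold). In all, 66 genes rose and 62 fell of 13455 tested, with 1416 at an unadjusted p under 0.05.

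FOXQ1 rose by 13.16 ± 1.06 from below background, at least 1734-fold, and by 11.15 ± 1.06 with levels under background set to it. On that basis the changes of FOXA2, CER1, EOMES and MIXL1 were 9.60, 9.28, 8.39 and 6.32. From below background PLSCR2 rose at least 713-fold, LINC00261, a noncoding RNA next to FOXA2, at least 244-fold and LINC00479 at least 77.4-fold. The natriuretic peptide gene NPPB rose by 9.42, with a change of 9.32 on its other probe, and the trypsinogen gene PRSS1 rose at least 93.2-fold. APOA2, an apolipoprotein, rose by 8.48 (478-fold), and the chemokine receptor gene CXCR4 by 8.31 (255-fold). By limma, the adjusted p of these 8 genes ran up to 0.0174, for NPPB.

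Among the genes that fell, HOPX had a change of −6.04 ± 0.78 (adjusted p = 0.0149, limma; −4.51 with levels under background set to it), again with −0.16 on its other probe. ZNF750 fell with −5.40, LGALS16 with −5.07, the homeobox neighbours DLX5 and DLX6 with −5.07 and −4.85, VTCN1 with −4.96 and VGLL1 with −4.93. AMER2 (−4.90), BNC1 (−4.88), KRT23 (−4.70), ANXA9 (−4.60) and WNT6 (−4.52) fell as well. With levels under background set to it, ZNF750 (−3.74), LGALS16 (−3.04), VGLL1 (−3.94) and BNC1 (−2.86) were no longer past the threshold. DLX5 was 33.5-fold and VTCN1 30.04-fold lower at 100 than at 0 ng/ml. INHBB, which encodes an activin subunit, fell by 4.05 ± 0.67 (adjusted p = 0.0373), with −2.50 when levels under background were set to it, and the Notch target HES5 fell by 2.75 ± 0.48 (adjusted p = 0.0444).

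**Figure D2:**
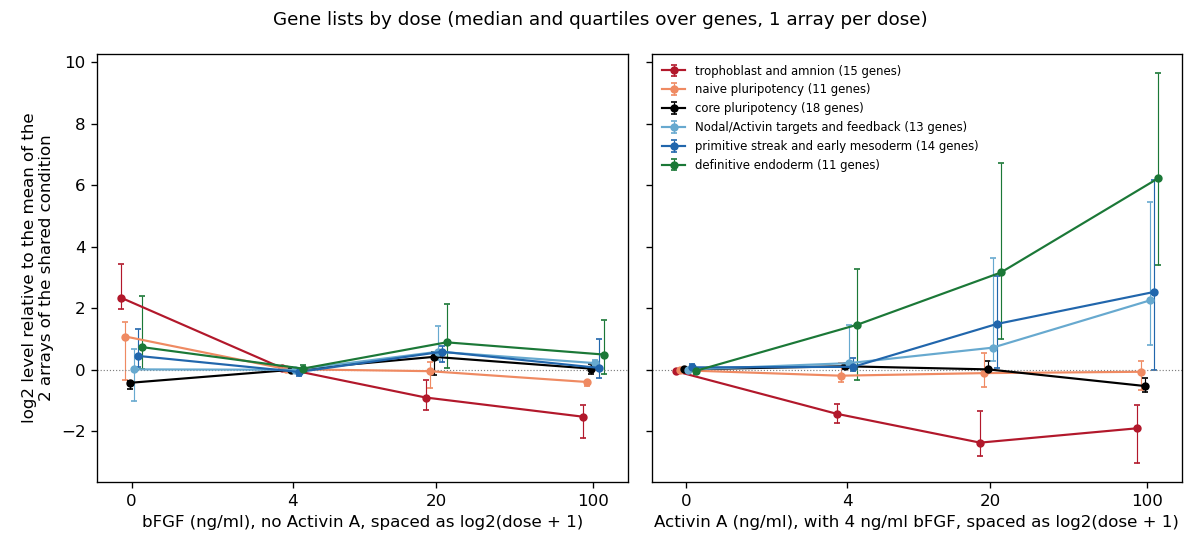
Median log2 level of 6 gene lists relative to the mean of the shared condition (y axis; bars are quartiles over genes) against the dose of bFGF (left) or Activin A (right) on x axes in ng/ml, with 1 array per dose. The trophoblast and amnion list went from 2.34 without bFGF to −1.53 at 100 ng/ml, and the definitive endoderm list reached 6.22 at 100 ng/ml Activin A.

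With Activin A 10 of the 23 lists passed the list test. All 11 tested genes of the definitive endoderm list had positive changes, with a median of 6.39 (adjusted p = 6.99e-16, limma camera, and adjusted p = 0.0568 with an estimated correlation). FOXA2, CER1, CXCR4 and APOA1 rose, 4 in all, and 8 rose when adjusted over the list alone. SOX17 had a change of 10.77 ± 2.03 (adjusted p = 0.0556, or 0.0133 with levels under background set to it) and GATA6 6.39 (adjusted p = 0.0694). This list's median stood at 1.46, 3.16 and 6.22 above the shared condition at 4, 20 and 100 ng/ml. Nodal and Activin targets had a median of 2.30 over 13 genes, with 5 past the threshold and 9 when adjusted over the list alone (adjusted p = 1.40e-13, limma camera, and adjusted p = 0.0989 with an estimated correlation). Besides NODAL, the LEFTY genes and CER1, PMEPA1 rose by 2.74 ± 0.47 (adjusted p = 0.0440).

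The primitive streak and early mesoderm list had a median of 2.72 over 14 genes (adjusted p = 9.99e-09, limma camera, and adjusted p = 0.162 with an estimated correlation). GSC, EOMES, MIXL1, WNT3 and FGF8 rose and HAND1 fell, and 8 rose and 1 fell when adjusted over the list alone. MIXL1 rose by 6.92 ± 1.18, WNT3 by 4.20 ± 0.50 and FGF8 by 4.84 ± 0.49, against a value of −0.30 ± 0.48 for the mesoderm factor MESP1. The trophoblast and amnion list went down here too, with a median of −1.99 (adjusted p = 2.50e-11, limma camera, and adjusted p = 0.212 with an estimated correlation). Of its 15 genes CGA, VGLL1, DLX5 and HAND1 fell, 4 in all, and 9 fell when adjusted over the list alone. Its median had already reached −1.44 relative to the shared condition at 4 ng/ml and was −2.37 and −1.91 at the higher doses.

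FGF/ERK targets had a median of 0.86 over 21 genes (adjusted p = 7.93e-09, limma camera, and adjusted p = 0.0568 with an estimated correlation). SPRY4 rose by 1.59 ± 0.28 and EPHA2 by 2.49 ± 0.44, and 4 members rose when adjusted over the list alone. In the matrix and integrin list, with a median of 0.63 (adjusted p = 0.000156, limma camera, and adjusted p = 0.318 with an estimated correlation), CDH2, the N-cadherin gene, rose by 3.86 ± 0.61. Over that list alone 6 rose and 1 fell. The fibroblast list had a median of 0.37 (adjusted p = 0.00362, limma camera, and adjusted p = 0.466 with an estimated correlation), with 4 rising when adjusted over the list alone and none over all genes. TAGLN had a change of 3.25 ± 0.63 and ACTA2 1.87 ± 0.37, both smooth muscle and contractile fibre genes, while the collagen gene COL1A1 had −0.32 ± 0.37. The mouse feeder cells are fibroblasts too. Their RNA may bind to probes of this list, and these arrays cannot separate it from that of the human cells. The stress list reached a median of 0.42 (adjusted p = 0.00520, limma camera, and adjusted p = 0.334 with an estimated correlation) and p53 targets 0.30 (adjusted p = 0.0260, limma camera, and adjusted p = 0.212 with an estimated correlation), with no single gene past the threshold and none when adjusted over the list alone. The neural crest list, of which 5 genes could be tested, had a median of −1.29 (adjusted p = 0.00557, limma camera, and adjusted p = 0.162 with an estimated correlation). DLX5 fell there, and 3 fell when adjusted over the list alone.

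Core pluripotency genes had a median change of −0.55 with Activin A and did not pass (adjusted p = 0.0830, limma camera). GDF3, a TGF-beta family ligand, rose by 2.53 ± 0.36 (adjusted p = 0.0208), while NANOG had a change of 1.05 ± 0.33, POU5F1 0.22 ± 0.40 and SOX2 −1.20 ± 0.41. SOX2 read 5.89 without Activin A and 4.66 at 100 ng/ml.

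The Activin A count of 128 genes also rests on single arrays. It was 0 without the 100 ng/ml array (294 at an unadjusted p under 0.05), 263 without 20 ng/ml, 66 without the shared-condition array of the bFGF series, 165 without that of the Activin A series (119 rose and 46 fell, 72 of them among the 128) and 17 without the 20 ng/ml bFGF array, where 2735 had an unadjusted p under 0.05. A step from 0 to any dose gave 0 genes (145 unadjusted), and fitting the series alone gave 29 (2889 unadjusted).

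In both series 33 genes fell, against 0.350 expected if the 2 sets were independent (Fisher's exact test p = 6.79e-61, over genes that are not independent). That expectation leaves out that the series share a condition and a fit. In 20 simulations of genes without change, with the 2 arrays of the shared condition given the same deviation, a mean of 0 genes fell in both. How far sharing raises the overlap among genes that do change was not tested. With levels under background set to it 26 of the 33 still fell in both, without BNC1, CYP19A1, INSL4, LGALS16, SCUBE3, VGLL1 and ZNF750. The 33 include CGA, CYP19A1, INSL4, LGALS16, KRT23, VTCN1, VGLL1, HAND1, S100P, IGF2 and H19. With Activin A IGF2 fell by 3.56 ± 0.62 (adjusted p = 0.0458, limma), H19 had a change of −3.49 ± 0.39 (adjusted p = 0.0113), and CGA one of −4.34 ± 0.65 (adjusted p = 0.0231). GNA14, a G protein subunit, was the 1 gene that rose in both, by 1.63 ± 0.27 with bFGF and 3.79 ± 0.27 with Activin A. Its bFGF call was lost without the 0 or the 100 ng/ml bFGF array or any 1 array of the Activin A series. No gene moved past the thresholds in opposite directions. If the sets were independent, 0.0369 genes would rise with bFGF and fall with Activin A, and 0.373 the reverse, so this absence tells little. Across genes the fitted changes had a Pearson r of 0.136 and a Spearman rho of −0.033. In simulated genes without change r was 0.144, which the observed r does not exceed. There the 2 arrays of the shared condition were given the same deviation, as if from 1 culture, which the labels do not state. The covariance was 0.0866, against 0.0189 in those simulated genes. All of these were given the median residual SD of 0.268, while real genes differ in their spread. The gap between the 2 covariances therefore cannot be read.

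The difference between the Activin A and bFGF changes was tested directly, and 0 genes passed (limma, smallest adjusted p = 0.109), with 1371 at an unadjusted p under 0.05. So FOXA2, at 11.33 with Activin A and 0.73 with bFGF, is not shown to differ between the factors at this threshold. Without 1 array the count was 103 (the shared-condition array of the Activin A series), 30 (4 ng/ml Activin A), 3 (the shared-condition array of the bFGF series) or 1 (20 ng/ml Activin A).

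Blood and endothelial genes, of interest to the wider series, did not move as a list in either direction of culture. The list's median change was −0.02 with bFGF (adjusted p = 0.484, limma camera) and 0.28 with Activin A (adjusted p = 0.836), where its mean was −0.22 though the test pointed up. GATA2, which is also in the trophoblast list, fell by 4.57 with bFGF and was the 1 member past the threshold over all genes tested, while 1 rose and 2 fell with bFGF and 2 fell with Activin A when adjusted over the list alone. DNA methylation and Polycomb genes had a median of 0.03 with bFGF (adjusted p = 0.704), with a mean of −0.07 and a test that pointed down, and of −0.22 with Activin A (adjusted p = 0.221), where 12 of 16 genes were negative and fry, which compares the list with no other genes, gave an adjusted p = 0.0152. DNMT3B, a de novo methyltransferase, had changes of 0.32 ± 0.43 and −0.80 ± 0.43, and TET1 had 0.27 ± 0.40 and −0.20 ± 0.40.

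The other lists not past the threshold with bFGF had these medians, with the adjusted p of limma's camera. Nodal and Activin targets had 0.56 (adjusted p = 0.140), FGF ligands and receptors 0.22 (0.185), Activin receptors and SMADs −0.32 (0.452), WNT targets −0.15 (0.313), and primitive streak genes −0.05 (0.437). Neural crest genes had −0.25 (0.185), fibroblast genes −0.42 (0.160), cell cycle genes 0.27 (0.160), stress genes −0.06 (0.379), cholesterol synthesis −0.34 (0.148) and the matrix and integrin list −0.07 (0.258). Signs differed in 4 further lists. Definitive endoderm genes had a median of 0.43 but a mean of −0.21 and a test pointing down (0.755), and hypoxia genes 0.06 but −0.21 and down (0.621). Neuroectoderm genes had 0.09 with a mean of −0.02 and a test pointing up (0.704), and p53 targets 0.02 with a mean of −0.06 and a test pointing up (0.866).

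With Activin A the remaining lists had medians of −0.25 for naive pluripotency (adjusted p = 0.574, limma camera), 0.28 for FGF ligands and receptors (0.306), −0.14 for the IGF axis (0.611), −0.05 for the cell cycle (0.834), 0.0064 for hypoxia (0.574) and 0.32 for cholesterol synthesis (0.103). In the IGF axis list IGF2 and H19 fell. BMP targets had a median of −0.18 and a mean of 0.41 with a test pointing down (0.574), in which BMP2 rose by 6.54 ± 0.82 and ID4 fell by 2.57 ± 0.34. WNT targets had −0.24 and a mean of 0.27 with a test pointing down (0.574). Activin receptors and SMADs had −0.03 and a mean of −0.02 with a test pointing up (0.599), and neuroectoderm genes 0.06 and a mean of −0.10 with a test pointing up (0.834).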

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

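The comparison of trophoblast genes with other cell type genes and its repeat after quantile normalization, the test on the number of hepatic genes and the setting of levels under background to it were chosen after the result was seen, and the choice of members in the further placental and hepatic lists was changed after a first result.

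The array at 20 ng/ml bFGF stood apart from its neighbours. The SD over genes of its deviation from the mean of the 4 and 100 ng/ml arrays was 0.605 log2, against 0.179 for the 4 ng/ml and 0.276 for the 20 ng/ml Activin A array, and 0.437 for the 4 ng/ml bFGF array, which has the 20 ng/ml array as a neighbour. A scaling that varies with brightness is argued against as the whole source, since that SD was still 0.569 after quantile normalization, and its ratio to the 4 ng/ml Activin A array, the comparison set in advance, went from 3.38 to 3.16, where scaling alone would have left at most 1.5. Different probes of 1 gene deviated together, with an intraclass correlation of 0.677 (bootstrap 95% interval 0.652 to 0.70, 3176 genes), against 0.331 for the 4 ng/ml Activin A array's deviation and 0.090 for the difference between the arrays of the shared condition, so a shift in the RNA of that sample may be behind it. Spike-in control spots, which no comparison uses, had a mean of 4.50 log2 on this array over 6 spots, against 3.49 to 3.76 on the other 7 arrays, so RNA amount, quality or labelling stay open beside a change in the culture, and the dose itself stays open and untested, since this dose has 1 array.

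Trophoblast and amnion genes were high without bFGF, with a median of 2.34 above the shared condition and 15 of 15 genes higher. Array scaling is argued against by a median of 2.33 after quantile normalization. The list's median was 2.17 above that of 59 genes of 6 other cell type lists (two-sided permutation p over genes = 0.00014). That p-value decides no cause, since the list was chosen as high on this array and its genes are not independent (estimated correlation 0.547). The lists did not rise alike. Definitive endoderm (median 0.73, or 0.48 with levels under background set to it) and fibroblast genes (median 0.58) were higher on that array too, and neuroectoderm genes were not (−0.19). The endoderm median was also 0.89 at 20 and 0.49 at 100 ng/ml bFGF, so its rise was not particular to the culture without bFGF. The fibroblast median was 0.42 and −0.02 at these doses. Whether RNA of the mouse fibroblast feeders reached the fibroblast probes was not tested. A loss of undifferentiated cells that raised some types more than others stays open. In a further placental list the median over 25 members above background was 0.64, above the central 95% of 10000 matched random lists (up to 0.207; 0.63 and 0.202 with levels under background set to it), with changes of 3.09 for HSD17B1, 3.08 for CYP11A1, −1.06 for PAPPA and −0.38 for KISS1, and of 2.01 for SDC1 and 2.73 for CAPN6, the brightest probes (levels 4.44 and 3.59). As 80% of the members were higher where more than 80% had been asked for, cells of trophoblast type in that culture may account for the pattern but this stays undecided, along with a change of these genes within stem cells. A first run on the 11 members that met the filter of 2 bright arrays gave a median of 0.10 at the 89.0th percentile, which spoke against such cells, but that filter removes genes bright on 1 array and was not part of the written rule.

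AFP and TTR, a fetal serum protein and a thyroid hormone carrier, did not follow the Activin A dose step by step. From the lowest to the highest dose AFP read −2.50, 1.12, −1.73 and −0.28, and TTR read −6.42, 1.68, 0.81 and 2.54. APOA4 (−7.37, then −1.67, −5.88 and −4.24, from the shared condition on) and APOC3 (−7.42, then −3.53, −7.41 and −4.77, where readings under about −5.44 are background), whose values had been seen, had their highest value at 4 ng/ml, like AFP. Unrelated bright spots are argued against, since, with levels under background set to it, 3 of 11 hepatic and visceral endoderm genes above background and not looked at before were higher by 1 or more (RBP4 2.46, AHSG 1.76 and FGB 1.17), as in 2 of 10000 matched random lists (one-sided permutation p over random draws of genes = 0.0003), although the rule set in advance for bright spots, a median of the 11 within the central 95% of matched lists (−0.10 to 0.12), was met and the count replaced it afterwards. Cells of hepatic or visceral endoderm type stay open, since that median was 0.0066, at the 41.5th percentile of matched lists (8 members that met the filter, in a first run, −0.0024 at the 35.9th), where the written rule spoke against such cells at or under the 50th, but 7 of the 11, such as APOE at 8.72, were already bright in the shared condition and would hide a small share, which makes the median undecided for both explanations.

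Probes without a gene symbol are outside the gene comparisons, and 24 of 4817 tested passed the threshold of the bFGF trend (14 rose, 10 fell), 22 that of the Activin A trend (13 rose, 9 fell) and 2 that of the difference.

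Other orders of the doses were tried for each count. In the bFGF series 1 of 12 orders, the labelled one, gave as many as 84 genes and the highest other gave 49, and in the Activin A series 1 of 12 gave as many as 128 and the highest other gave 1. These orders are too few for a share under 0.05. Over both series jointly, 1 of 100 orders drawn from 144 gave as many as 212 genes, the labelled one, and the highest other drawn gave 35. Not all 144 were tried, and 1 other bFGF order alone gave 49, so the highest of all may lie above 35. Among the orders drawn, the share argues against a chance order of the doses for the sum. With 1 array per dose, this share does not tell the dose from other differences between arrays that run in the same order.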

How the results depend on the processing

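Quantile normalization without the 20 ng/ml bFGF array and setting levels under background to it were chosen after seeing the data. No list or named gene past its threshold turned its direction in the alternatives computed for it, and the named genes were not recomputed for the threshold of 0.1, the estimated correlation or the quantile normalization without that array. Many calls were lost, though. Of 20 named bFGF and 24 named Activin A genes past the threshold, 0 and 7 still passed with a linear dose. These numbers were 10 and 6 with no filter and 7 and 4 without the 20 ng/ml bFGF array. They were 19 and 8 with each series alone and 19 and 24 with the dose as a rank. With levels under background set to it, 84 genes passed for bFGF (83 of them among the original ones), 121 for Activin A (117), and the same 6 and 10 lists. With the dose as a rank, centring on the median, the mean of the probes, or eBayes with trend or robust, the bFGF count lay between 76 and 110 genes and the Activin A count between 116 and 154. With the dose as a rank 1 gene passed for the difference of the changes. A step from 0 to any dose gave 13 and 0 genes for bFGF and Activin A (1556 and 145 at an unadjusted p under 0.05) and 3 bFGF lists. A linear dose gave 2 genes for bFGF, both of which rose, where 8 had risen and 76 fallen. It gave 308 genes for Activin A, 54 of them among the original ones, 15 for the difference and 3 bFGF lists. Without the series term the Activin A count was 494 and the difference 1, and each series alone gave 412 and 29 genes (1097 and 2889 at an unadjusted p under 0.05). Quantile normalization gave 53 and 76 genes, 52 and 75 of them among the original ones, and also without the 20 ng/ml bFGF array 8 and 5. No filter gave 34 and 11 genes, a stricter filter 28 and 56, and a threshold of 0.1 gave 183 and 237. With an estimated correlation 0 lists passed in either trend (4 and 5 unadjusted). The SD between the arrays of the shared condition was 0.435 with no filter and 0.101 with the stricter one, which follows from the dim genes let in or kept out. For the other changed counts the cause was not tested.

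Leaving out 1 array at a time gave 6 to 416 genes for bFGF, 0 to 263 for Activin A and 0 to 103 for the difference. The bFGF count was 6 without 0 ng/ml, 13 without 20 ng/ml, 416 without 100 ng/ml, and 180 or 138 without the shared-condition array of the bFGF or the Activin A series. For Activin A the count was 0 without 100 ng/ml, 263 without 20 ng/ml, 66 without the shared-condition array of the bFGF series, 165 (119 rose, 46 fell) without that of the Activin A series and 17 without 20 ng/ml bFGF (2735 unadjusted). For the difference it was 103 without the shared-condition array of the Activin A series, 30 without 4 ng/ml Activin A, 3 without that of the bFGF series and 1 without 20 ng/ml Activin A. Of the lists 4 to 6 passed for bFGF, at least 4 of them among the original 6, and 9 to 12 for Activin A, at least 7 of them among the original 10. The trophoblast list passed in both trends under 21 of 22 alternatives, with medians of −5.51 to −2.39 for bFGF and −3.61 to −0.92 for Activin A. BMP targets were lost under 6 of 22, and so was the fibroblast list for Activin A. For bFGF core pluripotency (medians 0.12 to 1.16) was lost under 3 of 22, including without the 0 ng/ml array. For Activin A p53 targets (0.13 to 0.31) were lost under 5 of 22 and stress genes (0.10 to 0.75) under 3, both also without the 100 ng/ml array. Neural crest genes (−1.64 to −0.47) were lost under 4 of 20. The primitive streak list (0.38 to 3.28) was lost under 1 of 22, the estimated correlation. Signal limits the folds, since 80.5% of genes lay above background without bFGF and 77.1% on the 20 ng/ml bFGF array.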

Other observations

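The correlation tests in this part were chosen after the dose trends were seen.

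Single doses can be set beside the shared condition as values without a test, since each has 1 array. At 4 ng/ml Activin A, the lowest dose, LEFTY1, a Nodal inhibitor gene, read 2.83 above the shared condition, TTR at least 7.11 above it, from below background, and GATA3, a trophoblast factor, −1.85 from it. At 100 ng/ml GATA3 read −0.03 from it. Without bFGF LEFTY1 read −3.17 and GATA3 2.61 relative to the shared condition. At 4 ng/ml Activin A 34 genes read at least 2-fold higher and 124 at least 2-fold lower, against 687 and 670 at 100 ng/ml. Without bFGF these numbers were 686 and 286, and at 100 ng/ml bFGF 89 and 160. On the 20 ng/ml bFGF array they were 173 and 838.

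IGF2 was chosen after it was seen to fall in both series, like the trophoblast list, so its relation to that list restates this and does not test it. Over the 8 arrays its level had a Pearson r of 0.963 with the list's median (exact permutation p = 0.000298, adjusted p = 0.000942) and a Spearman rho of 0.929 (exact permutation p = 0.00223, adjusted p = 0.00298), both two-sided. Without the 2 arrays farthest from the median of the list r was 0.903. H19, the other of 2 relations computed, had an r of 0.955 (exact permutation p = 0.000471, adjusted p = 0.000942), a rho of 0.905 (exact permutation p = 0.00456, adjusted p = 0.00456) and an r of 0.914 without the same arrays. Whether IGF2 RNA comes from cells of trophoblast type stays undecided, since both measures follow the doses, the shared condition is counted as 2 of the 8 arrays and cell types were not separated.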
